A study of Danio rerio with 2 samples.

How the data were processed

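Single-cell RNA-seq libraries came from zebrafish embryos carrying an mCherry reporter under the flk (kdrl) promoter, which marks endothelium, and a GFP reporter under the cd41 (itga2b) promoter, which marks blood stem and progenitor cells and thrombocytes. Per the labels, embryos were collected at 52 hours after fertilisation, dissociated, and sorted for GFP, for mCherry and for both. The proportions in which the 3 sorted fractions entered a library are not given in the sources used here. One library came from uninjected embryos and 1 from embryos injected with 4 ng of a vegfc morpholino oligonucleotide (vegfc MO), an antisense reagent that blocks translation or splicing of its target. A library from embryos injected with a control oligonucleotide was not analysed here. Each group thus held 1 library, and the number of embryos behind each is not given in the sources used here.

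The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, as filtered matrices that the authors made from 10x 3' reads. The matrices came from Cell Ranger and the GRCz11 build, per the submitters' processing notes. The versions of Cell Ranger and of the gene annotation are not given in the sources used here. Each matrix held 28330 features, of which 3 were reporter sequences (mCherry, EGFP and ZsGreen, the last with 0 UMIs). A symbol shared by several Ensembl identifiers, of which there were 483, was kept as separate features, and reads of near-identical copies may have been split between them by the counting. No genome was used here, so gene positions are not given.

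Barcodes with under 200 genes or over 10% mitochondrial UMIs were removed. The uninjected matrix held 4438 barcodes and the vegfc MO matrix 2806, of which 3855 and 2654 passed. Scrublet, run per library in scanpy 1.11.5, marked 1 and 6 further cells as doublets, which were removed. A caller that marks so few cells is taken not to have worked, which was not tested, and doublets are taken to remain among the 3854 and 2648 cells analysed. Removal of the cells with the highest 5% of doublet scores was added as an alternative after the data were seen.

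Cells of both libraries were log-normalised and clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1) with scanpy 1.11.5, igraph 0.11.9 and umap-learn 0.5.12 under Python 3.11.15. No batch correction was applied. Genes of the response and cell cycle lists, ribosomal, mitochondrial and haemoglobin genes were left out of the clustering. A cluster took a class name from the marker list with the highest mean log2 fold over the other cells, after 10 CPM was added to each level. A name needed at least 3 markers raised 2-fold, a marker of the class among the 25 leading genes, and no more markers of another class than of its own among the first 10. A cluster whose cells in either library had a median depth under a 3rd of that library's also needed a marker among its first 10 genes. The marker lists were fixed in advance and this scoring rule was written later. Of 33 clusters, 24 took a name, falling into 12 classes, and 9 stayed unnamed. Names are "like" names, since no annotation by the authors was used.

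UMIs were summed per library and class and scaled by the class total to give CPM, the usual unit of counts at a fixed total. The ratio of vegfc MO to uninjected CPM is given on the log2 scale with a conditional exact 95% interval, and single levels carry exact Poisson intervals. Shares of cells carry exact Clopper-Pearson intervals. All of these cover counting error only. Because each group holds 1 library, no test between groups was possible, and no p-value, standard error or number of changed genes is given. A gene with 0 UMIs in a library has its fold given against a floor of 3 UMIs in that library. For 26 gene lists the median log2 ratio was taken over members with at least 20 UMIs in both libraries together, with an interval from 1000 Poisson draws. Its percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins, is a description of these libraries. To compare shares of cells with a UMI, each cell was thinned to 1500 UMIs and shallower cells were left out.

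Under CPM scaling the median of all genes was not at 0. It lay at 0.15 in endothelial-like cells, 0.20 in blood progenitor-like cells, 0.28 in thrombocyte-like cells and 0.21 in cluster 13, on the log2 scale. A gene or list at that value stands level with the bulk of genes, and list percentiles are relative to it. Counts of list members as higher or lower are taken against 0, except where the bulk is named.

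The groups, gene lists, marker lists, comparisons, named-gene rule and first set of alternatives were fixed before the data were examined. Named genes included vegfc, flt4, kdr, kdrl, flt1, itga2b, runx1, myb and gata2b, and not every gene and list fixed in advance is reported. In endothelial-like and blood progenitor-like cells, the 10 highest and the 10 lowest ratios were added, among genes with at least 100 UMIs, 50 CPM in 1 library and a UMI in 5% of the cells of 1 library. Clone-named and haemoglobin genes were passed over. Of each list, the 2 highest and 2 lowest members could be named. Other genes named in the text (hey2, hlfa, her6 and her9 across classes, hspa5 and her15.1 in the other blood classes, EGFP by cluster) were chosen after their values were seen.

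Alternatives were stricter cell filters (at least 500 genes, at most 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, all genes open to clustering, median-of-ratios scaling, the mean of CPM per cell, a total without haemoglobin, ribosomal and mitochondrial genes, thinned cells, and other UMI minimums. Those added after the data were seen were the removal of high doublet scores, the compared lists left out of clustering, clusters 4 and 13 pooled, and reporter transcripts in place of kdrl and itga2b. No columns of per-sample values were left unused.

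The ratio and list steps were tested on simulated data with known answers, drawn as Poisson counts from a profile pooled over both libraries. The intervals assume the same Poisson counts, and spread between cells or between libraries was not simulated. The test therefore checks the computation, and not how well the intervals cover these data. For endothelial-like cells, 18943 genes were simulated, and all 50 genes changed by each of 0.25-, 0.5-, 2- and 4-fold came out in the right direction. The intervals held the true value for 88%, 100%, 100% and 98% of these. For blood progenitor-like cells, with 17619 genes simulated, all 50 of each size also came out in the right direction, with intervals that held the true value for 96%, 92%, 96% and 96%. Of 200 unchanged lists, 4% in endothelial-like and 3.5% in blood progenitor-like cells lay outside the central 95% of random lists. Tables and intervals used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.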

Results

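The uninjected library held 38931352 UMIs over 4438 barcodes and the vegfc MO library 27977008 UMIs over 2806 barcodes. After filtering, 3854 and 2648 cells remained, with median depths of 6714 and 6679.5 UMIs and medians of 1751 and 1758.5 genes per cell. The comparison asks how loss of Vegfc, a ligand of the endothelial receptor Flt4 that drives venous sprouting and lymphatic development, relates to the makeup and expression of endothelial and blood cells at 52 hours after fertilisation. Each group has 1 library, so no difference below has a replicate check, and every difference is one between these libraries.

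The classes recovered included the sorted lineages and many cells outside them. Endothelial-like cells fell into cluster 0 (led by sele, lyve1a, lyve1b and stab1, with venous and lymphatic markers), cluster 1 (led by cxcr4a, esm1 and dll4, with arterial markers) and cluster 7 (led by clic2, hand2 and gata5, with endocardial markers). Blood progenitor-like cells formed cluster 4, led by zeb2b, gata2b and csf1rb, and thrombocyte-like cells formed clusters 8 and 9, which carried the most EGFP. Both were led by apln and gp1bb, with drl, rhag, tal1, gata1b and mpl in cluster 8, and rrm2 and pclaf in cluster 9. In the uninjected library, thrombocyte-like and blood progenitor-like cells had 49.5 and 48.4 CPM of runx1 and 330 and 236 CPM of myb. The name thus does not set thrombocytes apart from their progenitors. Cluster 13, led by histone genes and il7r, and cluster 2, led by s1pr4, cytip and ccr9a, stayed unnamed beside them. Mesenchyme- or cartilage-like cells, which lie outside the sorted lineages, made up 17.3% of the uninjected and 25.9% of the vegfc MO library, so neither sort held sorted lineages alone.

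**Figure D1:**
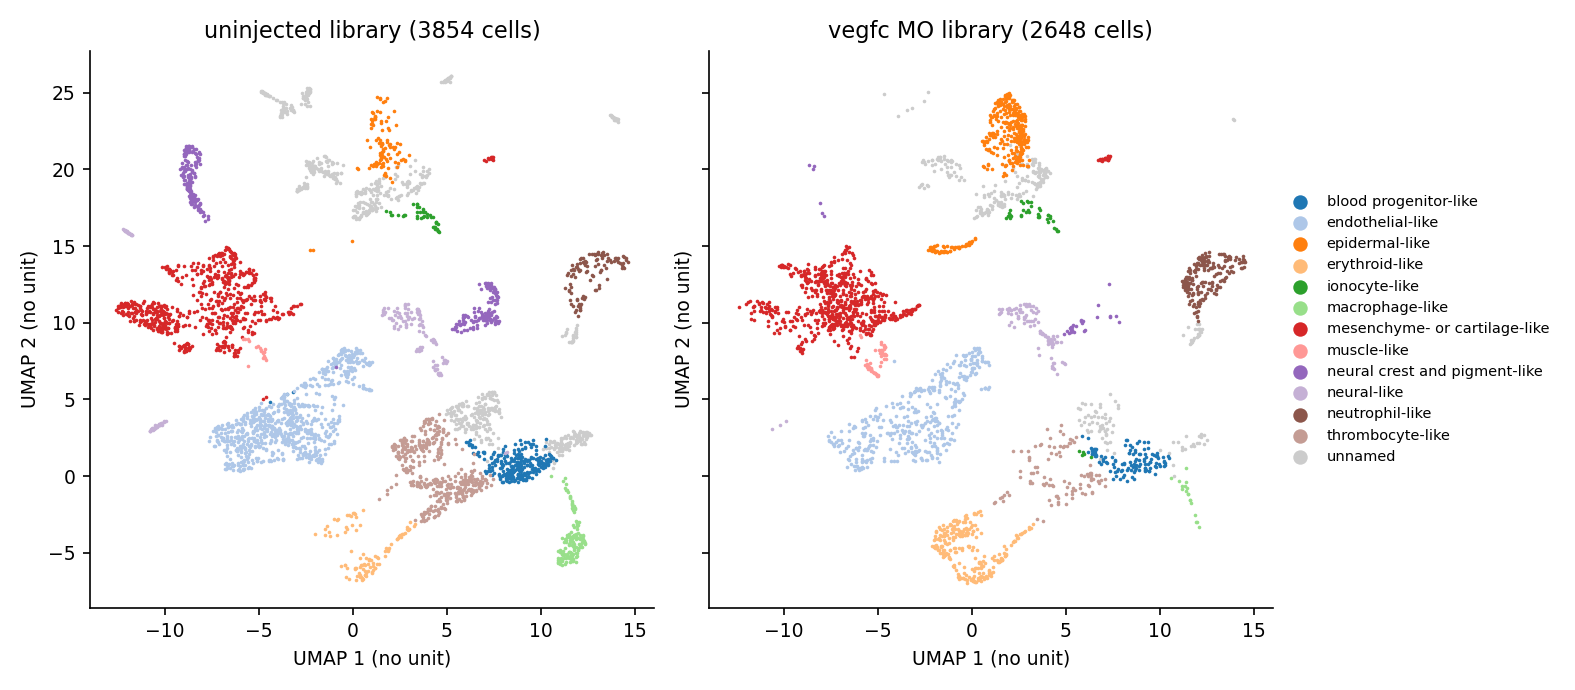
UMAP of the 3854 uninjected cells (left) and 2648 vegfc MO cells (right), with 1 point per cell coloured by class and axes without units. Thrombocyte-, macrophage- and pigment-like cells are denser in the uninjected panel, and epidermal-, erythroid- and neutrophil-like cells in the vegfc MO panel.

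The vegfc MO library held smaller shares of the sorted lineages than the uninjected library. Thrombocyte-like cells were 10.8% of uninjected cells (95% interval 9.88 to 11.9) and 3.93% of vegfc MO cells (3.22 to 4.74). Blood progenitor-like cells were 7.16% (6.37 to 8.02) and 4.68% (3.91 to 5.56), and endothelial-like cells 20.2% (18.95 to 21.5) and 15.4% (14.1 to 16.9). Blood progenitor-like cells per endothelial-like cell stood at 0.856 (0.665 to 1.098) of the uninjected value, an interval that holds 1. Macrophage-like cells were 3.79% and 0.680%, and cluster 13 was 4.54% and 2.00%. In the other direction, erythroid-like cells were 2.62% (2.14 to 3.17) and 9.25% (8.18 to 10.4), and neutrophil-like cells 2.72% and 7.33%.

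Classes outside the sorted lineages differed as much. Epidermal-like cells were 2.72% of uninjected and 12.9% of vegfc MO cells, muscle-like cells 0.467% and 2.00%, and ionocyte-like cells 1.12% and 1.55%. The ionocyte-like name is weak, since its cluster, 18, had 0 ionocyte markers among its first 10 genes. These included s100a11, agr2, fgb and muc5.1, with the markers foxi3a and trpv6 further down. Neural crest and pigment-like cells were 7.76% and 1.17%, and neural-like cells 4.36% and 3.66%. Cluster 32 (epidermal-like) held 3 uninjected and 62 vegfc MO cells, and cluster 3 (pigment-like) held 163 and 6, so each lies almost wholly in 1 library. Within endothelial-like cells, cluster 0 was 53.9% and 50.9%, cluster 1 was 25.8% and 21.8%, and the endocardial-like cluster 7 was a larger part in the vegfc MO library, at 20.3% (17.5 to 23.3) and 27.4% (23.1 to 32.0).

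The cells were sorted through GFP, mCherry and double-positive gates and pooled, so these shares are not read as shares in the embryo. When each library was clustered on its own, blood progenitor-like cells were 8.04% and 7.86%, but the vegfc MO library then held no thrombocyte-like cluster, so these shares are not of like classes.

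**Figure D2:**
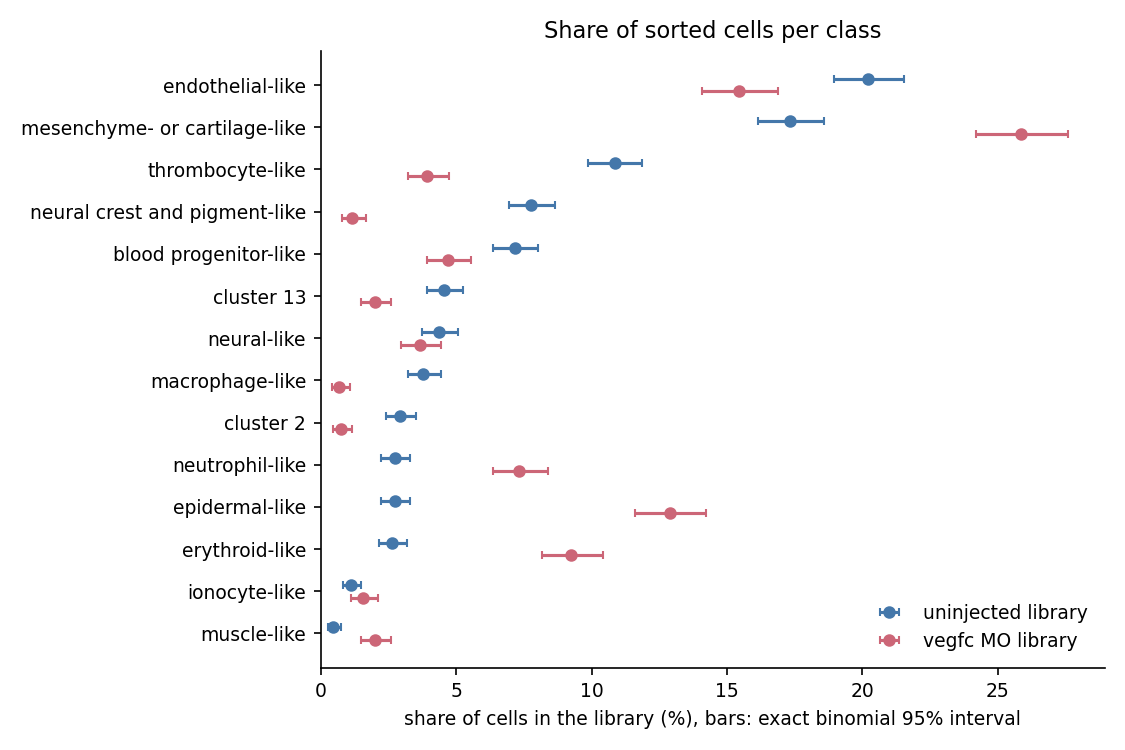
Share of the cells of each library in each named class and in clusters 2 and 13 (x axis, percent), with exact binomial 95% intervals as bars. Thrombocyte-like cells stand at 10.8% and 3.93%, and epidermal-like cells at 2.72% and 12.9%, with intervals that do not overlap.

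Transcripts of vegfc, the targeted gene, were not lower in endothelial-like cells of the vegfc MO library or over all its cells. In endothelial-like cells there were 114 UMIs in the uninjected library, or 30.6 CPM (25.3 to 36.8), and 117 in the vegfc MO library, or 57.5 CPM (47.6 to 69.0), a log2 ratio of 0.91 (0.52 to 1.29) that was 1.64 when cells were thinned. Over all cells the level was 8.78 CPM and 11.3 CPM, and in thrombocyte-like cells 8.81 CPM and 8.62 CPM, while neural-like cells had 10 and 0 UMIs. A morpholino blocks translation or splicing, so counts of 3' tags check neither the knockdown nor the labels.

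The receptors and co-factors of the Vegf pathway moved in both directions in endothelial-like cells. The Vegfc receptor flt4 stood at 37.9 CPM (31.9 to 44.7) in the uninjected and 32.0 CPM (24.7 to 40.7) in the vegfc MO library, a difference not detectable at this depth. The main Vegfa receptor of zebrafish endothelium, kdrl, was lower, at 997.5 and 760 CPM, with a log2 ratio of -0.39 (-0.48 to -0.31). The other Kdr gene, kdr, was at 70.16 and 67.4 CPM. The decoy receptor flt1 was higher, at 593 and 854 CPM (log2 ratio 0.53, 0.44 to 0.62). The co-receptor nrp2b was lower, at 174 and 109 CPM, and the ligands pgfb (18.3 and 38.9 CPM) and vegfaa (4.30 and 10.3 CPM) were higher. Of 12 members of the Vegf list measured, 7 were higher and 5 lower, with a median of 0.31 (0.04 to 0.45) at the 82.2 percentile of random lists. That median turned to -0.09 when members with 1 or more UMIs were taken.

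The venous and lymphatic list stood below the bulk of genes in endothelial-like cells of the vegfc MO library, with members on both sides, and the arterial list stood level with the bulk. The venous and lymphatic list had a median of -0.25 (-0.39 to 0.05), at the 0.05 percentile, with 10 of 17 members lower. Among these, osr2 (19.6 and 5.41 CPM) and mrc1a, a scavenger receptor of veins and lymphatics (47.3 and 28.5 CPM), were lowest, while mafba (39.2 and 54.1 CPM) was higher and ephb4a (12.6 and 16.7 CPM) did not differ detectably. The arterial list had a median of 0.14 (0.04 to 0.29), at the 39.0 percentile. It ranged from the junction genes cldn5b (7.79 and 2.95 CPM) and gja5a (6.18 and 2.95 CPM) to tbx20, a heart and endothelial transcription factor, at 46.5 and 111 CPM. The arterial median exceeded the venous and lymphatic one by 0.38 (0.06 to 0.59).

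This difference was not uniform over clusters. It was -0.14 in cluster 0, 0.49 in cluster 1 and 0.42 in cluster 7. Summed arterial genes were at 4704 and 4197 CPM in cluster 0, 13329 and 16204 CPM in cluster 1, and 2868 and 4246 CPM in cluster 7. Summed venous and lymphatic genes were at 2080.0 and 2004 CPM, 676 and 695 CPM, and 327 and 405 CPM in the same order. Cluster 7, where these sums were lowest, made up 20.3% and 27.4% of endothelial-like cells. Values of the pooled class therefore mix the levels within clusters with the makeup of the class, and these were not separated. Summed over members, arterial genes gave 6624 CPM (6542 to 6707) in the uninjected and 7058 CPM (6943 to 7175) in the vegfc MO library, and venous and lymphatic genes 1220 CPM (1185 to 1256) and 1179 CPM (1133 to 1228). The arterial median became -0.01 with median-of-ratios scaling and -0.05 with the mean of CPM per cell, and the difference of the medians was 0.05 with the latter and 0.67 with stricter cell filters.

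Inflammatory genes were higher as a list in endothelial-like cells of the vegfc MO library. The NF-kB and inflammatory list had a median of 0.85 (0.58 to 0.91), at the 100 percentile, with tnfb at 6.45 and 18.2 CPM. Its highest member, mmp9 (4.30 and 29.0 CPM), is also a neutrophil marker, and the 9 measured neutrophil genes had a median of 2.25, although il6r (14.5 and 17.7 CPM) and mmp13a (ENSDARG00000012395, 4.57 and 5.41 CPM) did not differ detectably.

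Targets of Bmp and Tgf-beta signalling were higher as a list, with a median of 0.55 (0.37 to 0.60) at the 99.6 percentile and 9 of 12 members higher. Its member tgfbi, a secreted matrix protein, was lower, at 14.5 and 6.39 CPM. Feedback genes of Erk signalling were lower, with a median of -0.23 (-0.42 to -0.06) at the 0.79 percentile and 11 of 15 members lower. Among them, spry1 was at 132 and 65.9 CPM and dusp6, an Erk phosphatase, at 1892 and 1258 CPM. Under stricter cell filters the Erk median was 0.0002822.

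Genes of DNA replication were lower as a list in endothelial-like cells. The S phase list had a median of -0.56 (-0.65 to -0.25) at the 0 percentile, with 14 of 19 members lower. Its nucleotide enzyme dut was at 151 and 59.5 CPM and cdca7a at 18.0 and 5.90 CPM, while tyms was higher, at 11.02 and 18.7 CPM. Genes of G2 and mitosis stood near the bulk in the class as a whole (median 0.25, 77.0 percentile) but went apart by cluster, at -0.52 in cluster 0, 0.20 in cluster 1 and 0.79 in cluster 7. S phase genes were at -0.60, 0.39 and -0.77 in the same order. Thinned to 1500 UMIs, 37.2% (33.5 to 41.1) of 650 uninjected endothelial-like cells carried at least 2 UMIs of the G2 and M phase list. In the vegfc MO library 35.1% (30.0 to 40.4) of 342 such cells did, a difference not detectable at this depth. The unthinned shares were 58.8% and 59.2% at median depths of 3345 and 4106 UMIs, and 129 and 67 shallower cells were left out of the thinned ones. In mesenchyme- or cartilage-like cells, a class outside the sorted lineages with median depths of 4778 and 5638 UMIs, the thinned shares were 46.8% and 43.4%.

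Glycolysis and hypoxia genes were higher, with a median of 0.46 (0.26 to 0.59) at the 99.4 percentile. The enzyme gpia was at 28.8 and 74.3 CPM. In contrast, the glucose transporter slc2a1a had 22 UMIs in the uninjected and 0 in the vegfc MO library, 4.01-fold lower against the floor of 3 UMIs. The shear-stress and Klf2 list was lower at its median (-0.33, 1.91 percentile) but its members split. The flow-induced factor klf2a was lower, at 767 and 524 CPM, and klf4 (9.946 and 5.902 CPM) did not differ detectably. In contrast, piezo1 (32.53 and 57.55 CPM) and thbd (4.30 and 12.8 CPM) were higher. Immediate early and heat shock genes had a median of 0.03 (8.58 percentile) that hid opposite members, with fosab at 1739 and 811 CPM and hsp70l at 569 and 1310 CPM.

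Most remaining lists stood nearer the bulk of genes in endothelial-like cells. Pan-endothelial genes had a median of 0.09 (26.7 percentile), from egfl7 at 1880.0 and 1456 CPM to sox7 at 28.0 and 56.6 CPM. Notch pathway genes had -0.01 (5.23 percentile) and tip cell genes -0.04 (5.56 percentile), with the chemokine receptor cxcr4a at 951 and 688 CPM and aplnra at 495 and 954 CPM. Basement membrane genes had 0.27 (74.0), haemogenic genes 0.22 (63.2), the unfolded protein response 0.15 (40.3), interferon genes -0.01 (15.7) and cholesterol synthesis -0.02 (20.1), each with its percentile in brackets. Erythroid genes had 0.01 (26.1) and thrombocyte genes 0.43 (83.5), which turned below 0 with members of 1 or more UMIs, and 1 macrophage gene was measured, at 0.32. Far from the bulk, ribosomal protein genes had -0.31 (-0.14 with the mean of CPM per cell and -0.46 with median-of-ratios scaling) and mitochondrially encoded genes -1.06 (-1.13 to -0.90), both at the 0 percentile.

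**Figure D3:**
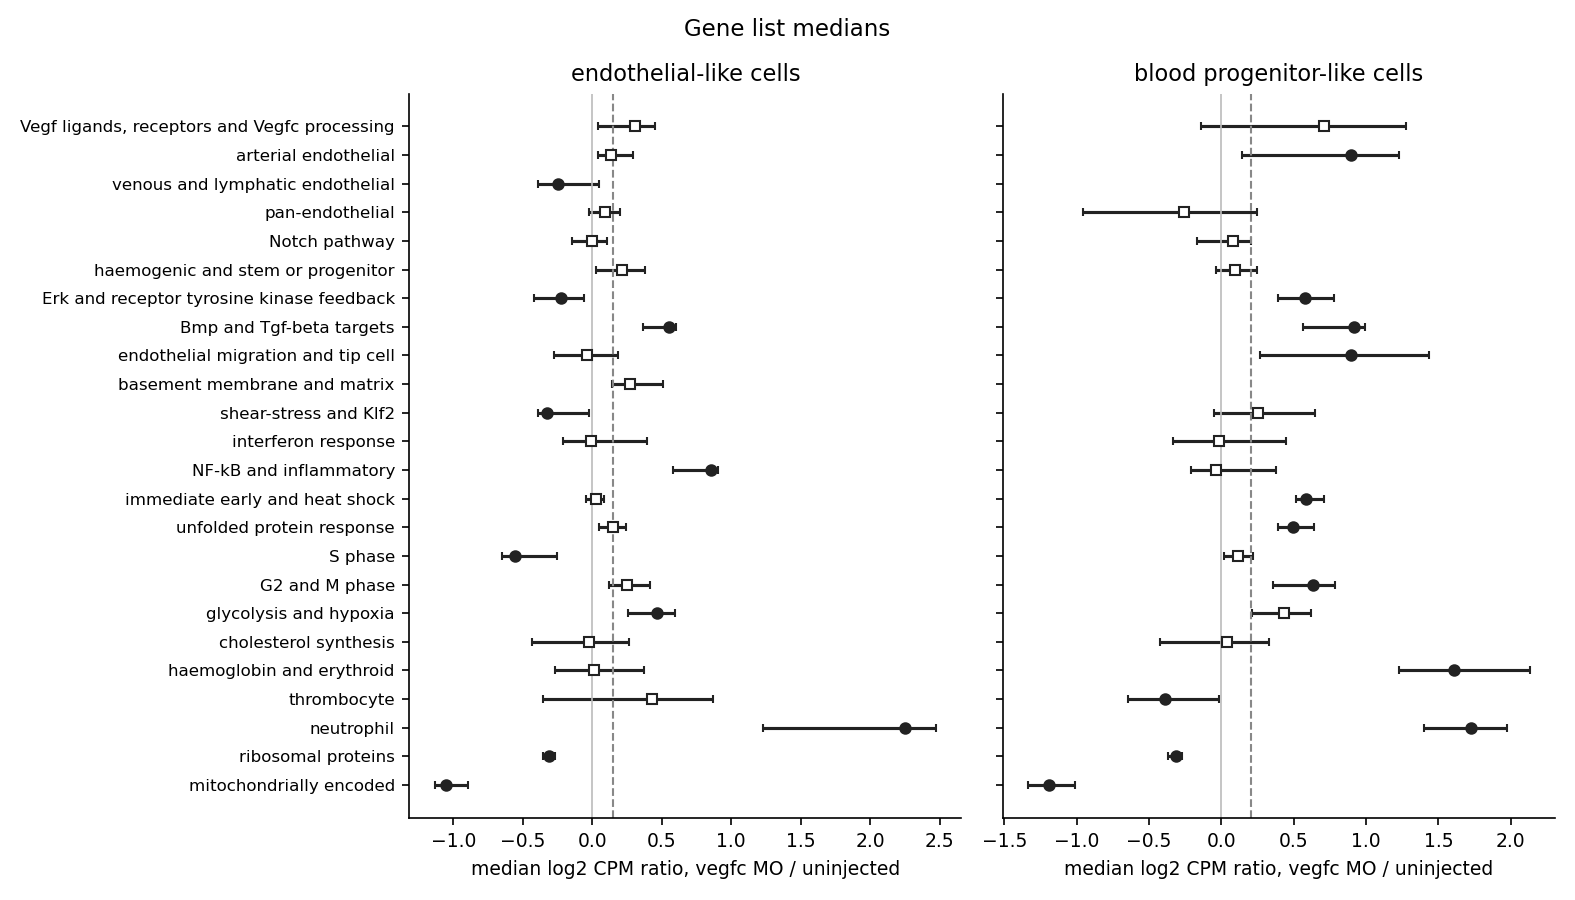
Median log2 CPM ratio of the reported gene lists with at least 3 measured members (x axis, vegfc MO over uninjected) in endothelial-like (left) and blood progenitor-like cells (right), with 95% intervals from Poisson draws and a dashed line at the median of all genes. Filled circles lie outside the central 95% of random lists, among them the Bmp and Tgf-beta targets at 0.55 and 0.92.

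Among single endothelial-like genes with at least 100 UMIs, 50 CPM and a UMI in 5% of cells, the latter 2 in at least 1 library, the lowest ratios in the vegfc MO library belonged to foxd1, a forkhead transcription factor (50.3 and 7.87 CPM, log2 ratio -2.67), the histone hist1h2a4 (identifier ENSDARG00000105400, a symbol shared with other copies and so uncertain; 379 and 77.2 CPM), and mid1ip1b (180 and 48.7 CPM). The complex I subunits mt-nd3, mt-nd1 and NDUFC1 followed, with log2 ratios of -1.87, -1.36 and -1.31, together with metrnlb, klf11a, the RNA-binding bicc1a and dut, between -1.54 and -1.34. The highest belonged to got1, the cytosolic aspartate aminotransferase (18.0 and 100.3 CPM, log2 ratio 2.48), lyz (2.41), and cebpa, a myeloid transcription factor (17.2 and 84.6 CPM, 2.30). Then came the cardiac troponin tnnt2a (1.95), the cytokine-binding crlf1a (1.78), the co-chaperone bag3 (1.71), brdt (1.70), the mitochondrial folate enzyme mthfd2 (1.54), the polycomb gene cbx7a (1.52) and thioredoxin txn (1.50).

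Part of this list was shared by the whole library. Of 8 lower genes measured in at least 4 other classes, hist1h2a4, mt-nd3, mt-nd1 and NDUFC1 had ratios below 0 in each of the 8 other classes. The nearest to 0 were -0.21, -1.07, -0.94 and -0.71 in the same order, with hist1h2a4 near level in blood progenitor-like cells (9.98 and 8.64 CPM). Of 8 such higher genes, brdt and mthfd2 had ratios above 0 in each of the 8 and bag3 in the 4 where it was measured. For got1 the level was alike in neural-like cells (37.0 and 37.2 CPM), with ratios above 0 in the others. The ratio of cebpa was above 0 in 5 of the 6 other classes where it was measured, among them mesenchyme- or cartilage-like cells (24.4 and 108 CPM). Within endothelial-like cells the log2 ratio of cebpa was 2.497 in cluster 0 and 2.365 in cluster 7, but -2.476 in cluster 1. The neutrophil lysozyme lyz had a UMI in 21.3% and 68.2% of endothelial-like cells and in 21.1% and 64.5% of mesenchyme- or cartilage-like cells, which should lack it, so it is read as background. In tnnt2a, 2.44% and 5.38% of endothelial-like cells carried a UMI.

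**Figure D4:**
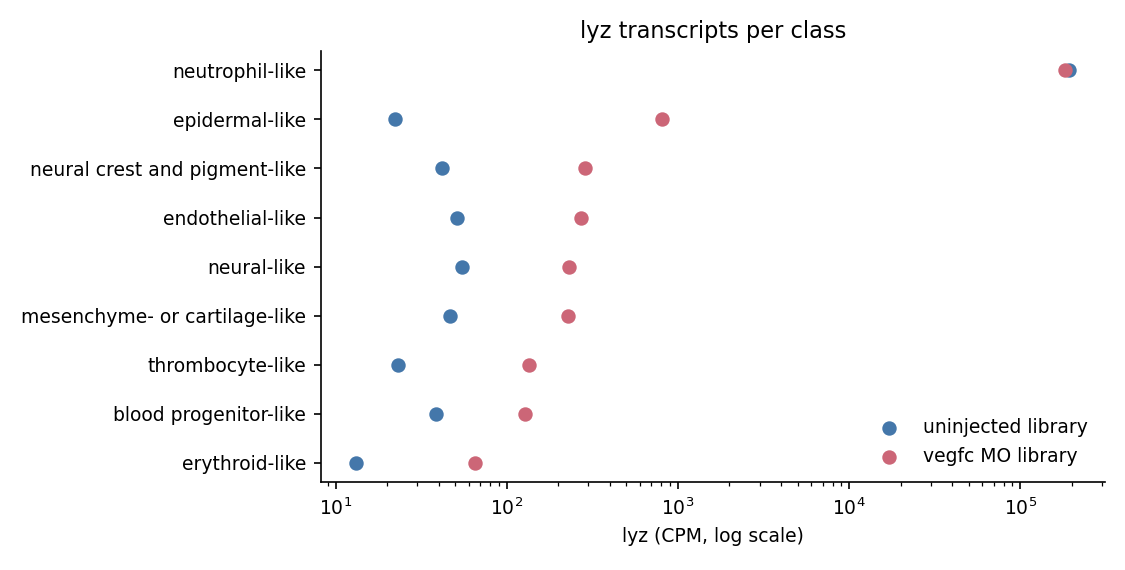
Level of lyz per class (x axis, CPM on a log scale) in the uninjected and vegfc MO libraries, with 1 point per library. Outside neutrophil-like cells every class shown is higher in the vegfc MO library, at 51.1 and 271 CPM in endothelial-like and 46.7 and 227 CPM in mesenchyme- or cartilage-like cells. In epidermal-like cells of the vegfc MO library, 1 cell held 3485 of the 3936 lyz UMIs. Cluster 13, not shown, went the other way, at 816 and 61.4 CPM, although 39.4% and 64.2% of its cells carried a UMI.

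In blood progenitor-like cells the regulators of stem and progenitor identity did not move together. The transcription factor runx1, required for blood stem cell emergence from endothelium, was lower in the vegfc MO library, at 48.4 CPM (41.82 to 55.7) and 29.1 CPM (20.5 to 40.1), a log2 ratio of -0.74 (-1.28 to -0.22). In contrast, gata2b was higher, at 111 CPM (101 to 122) and 225 CPM (200.1 to 253), and so was myb, at 236 CPM (221 to 252) and 392 CPM (358 to 428). The Notch-induced repressor hey2 was at 84.6 and 21.2 CPM (log2 ratio -2.00), hlfa at 101.0 and 50.3 CPM and gfi1aa at 62.4 and 29.1 CPM. The haemogenic list as a whole had a median of 0.09 (-0.03 to 0.25) at the 26.0 percentile, with 8 of 13 members higher, and kita (2.245 and 10.21 CPM) and tal1 (10.98 and 25.1 CPM, log2 ratio -0.41 when cells were thinned) highest. Notch pathway genes had 0.08 (29.9 percentile), from her12 at 24.2 and 2.36 CPM to notch1b at 10.48 and 21.2 CPM. The direction of that list turned with the setting, from 0.40 under stricter cell filters to -0.28 when cells were thinned and -0.54 with the mean of CPM per cell, and the haemogenic list was -0.11 with median-of-ratios scaling.

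In cluster 13 and thrombocyte-like cells runx1 and gata2b went the same way. In cluster 13, runx1 was at 53.9 and 29.0 CPM, gata2b at 75.0 and 191 CPM and myb at 160 and 325 CPM, and in thrombocyte-like cells runx1 was at 49.5 and 32.1 CPM and gata2b at 23.1 and 76.8 CPM. Here myb (330.0 and 389 CPM, log2 ratio 0.24) stood below the median of all genes, and its ratio was -0.04 with median-of-ratios scaling. The runx1 ratio in thrombocyte-like cells was -0.62 (-1.13 to -0.15), and 0.48 when cells were thinned. The gata2b difference was 2.44 in cluster 9 and 0.52 (-0.23 to 1.202) in cluster 8. In the small cluster 2, gata2b was level (32.4 and 32.5 CPM) and runx1 had 41 and 3 UMIs, and in endothelial-like cells runx1 had 22 and 21 UMIs. In neutrophil-like cells runx1 was lower, with a log2 ratio of -1.16 (-1.955 to -0.3805), and in erythroid-like cells it had 2 and 22 UMIs. The lower hlfa level was not limited to these blood groups. Its log2 ratio was -0.9478 in endothelial-like cells, -1.236 in neutrophil-like cells and -1.201 in cluster 2. In erythroid-like cells hlfa did not differ detectably (-0.1285, -0.7065 to 0.4737).

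**Figure D5:**
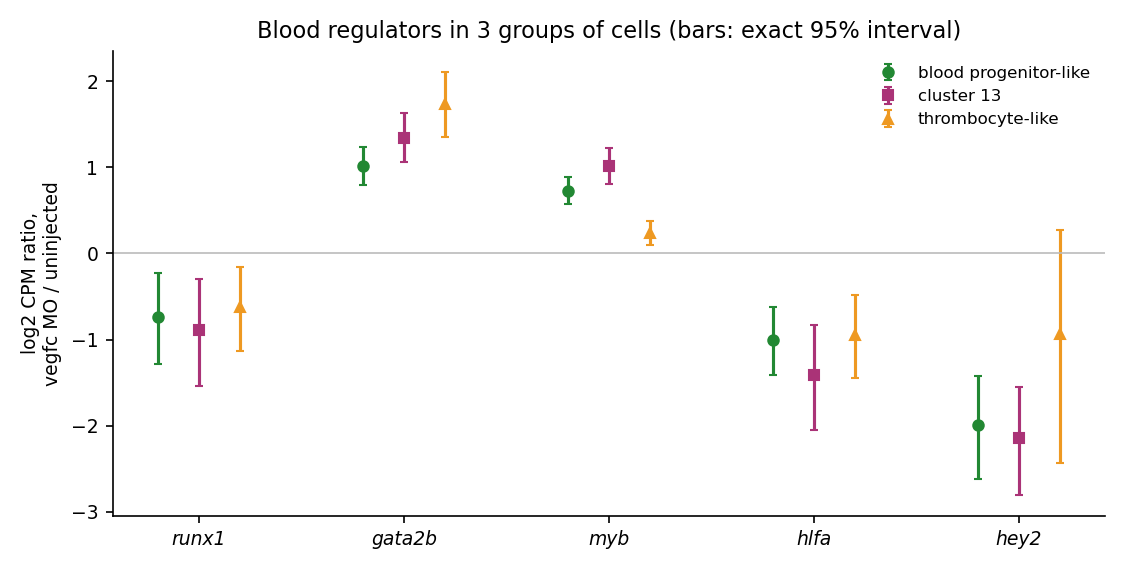
Log2 CPM ratio (y axis, vegfc MO over uninjected) of 5 blood regulators in blood progenitor-like cells, cluster 13 and thrombocyte-like cells, with exact 95% intervals as bars. All 3 groups lie below 0 for runx1 and hlfa and above 0 for gata2b, at -0.74, -1.01 and 1.02 in blood progenitor-like cells.

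The G2 and M phase genes were higher as a list in blood progenitor-like cells. Their list had a median of 0.63 (0.35 to 0.79) at the 100 percentile, with 18 of 22 members higher, such as the mitotic kinase aurka at 9.98 and 33.8 CPM and cenpf at 38.4 and 86.4 CPM. S phase genes were level with the bulk (0.11, 24.3 percentile). At 1500 UMIs, 72.2% (66.2 to 77.8) of 245 uninjected and 68.8% (58.4 to 78.0) of 93 vegfc MO cells carried at least 2 UMIs of the G2 and M phase list, against 95.7% and 89.5% unthinned, with 31 cells left out in each library. With at least 5 UMIs of the list, the thinned shares were 29.4% and 32.3%, so their order turned.

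The unfolded protein response was higher as a list (0.49, 99.7 percentile), although manf (0.23, -0.12 to 0.57) and creld2 (0.24, -0.63 to 1.05) stood level with the bulk. Its chaperone hspa5 was at 322 and 634 CPM and ddit3 at 220 and 477 CPM. Immediate early and heat shock genes were higher in 22 of 24 members (0.58, 100 percentile), with junbb at 181 and 387 CPM. Bmp and Tgf-beta targets (0.92, 99.9 percentile) were led by bambia (13.5 and 29.9 CPM) and smad6a (8.73 and 18.1 CPM, log2 ratio -0.92 when cells were thinned). Glycolysis and hypoxia genes had 0.43 (97.3 percentile), with igfbp1a at 35.4 and 130 CPM. Erk feedback genes had 0.58 (97.8 percentile), from spry1 at 14.2 and 4.71 CPM to dusp4 at 4.99 and 21.2 CPM, and -0.02 with the mean of CPM per cell. The arterial list rested on 7 measured genes (0.90, 99.8 percentile), with efnb2a at 15.5 and 59.7 CPM, and was -0.11 when cells were thinned.

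Genes of other blood lineages moved apart in blood progenitor-like cells. The 4 measured thrombocyte genes had a median of -0.39 (2.08 percentile) but split: the thrombopoietin receptor mpl (35.7 and 18.1 CPM) and gp1bb (32.7 and 18.1 CPM) were lower, rgs18 was level (57.1 and 60.5 CPM) and apln was higher (5.99 and 16.5 CPM). These directions were not stable, with gp1bb at 0.44 when each library was clustered on its own, apln at -0.28 with all genes open to clustering, and the list at 0.07 with members of 1 or more UMIs. Erythroid genes were higher (1.61, 100 percentile), with the globin hbae3 at 13.7 and 96.6 CPM, while hbae1.1 was level, at 70.34 and 69.91 CPM. The globin hbbe1.1 was higher both there (6.735 and 21.2 CPM) and in classes that should lack it, at 7.88 and 29.8 CPM in mesenchyme- or cartilage-like and 6.24 and 84.1 CPM in epidermal-like cells. Also higher as a list were neutrophil genes (1.73, 100 percentile), with scpp8 at 20.2 and 126 CPM, while il6r (192 and 179.9 CPM) and cebp1 (9.73 and 7.86 CPM) did not differ detectably. Both lineages made up larger shares of the vegfc MO library. Inflammatory genes had -0.04 (7.65 percentile), which turned above 0 under stricter cell filters, and interferon genes -0.01 (17.8 percentile). Among inflammatory genes, tnfb had 51 and 0 UMIs, 5.40-fold lower against the floor of 3 UMIs. Ribosomal protein genes had -0.32 and mitochondrially encoded genes -1.19, both at the 0 percentile. When each library was clustered on its own, the thrombocyte list had 3.38, in a class that is not alike between the libraries.

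Lists of vessel identity rested on few genes in these cells. Vegf genes had 0.71 (80.6 percentile, 3 measured), pan-endothelial genes -0.26 (8.62, 4 measured), tip cell genes 0.90 (98.3, 5 measured) and shear-stress genes 0.25 (54.4, 3 measured). The tip cell list ran from esm1 at 7.48 and 0.785 CPM to cxcl12a, a ligand of the chemokine receptor Cxcr4, at 3.49 and 21.2 CPM. Cholesterol synthesis genes had 0.04 (36.3, 5 measured). The pan-endothelial median turned above 0 with members of 1 or more UMIs, and the shear-stress median below 0 with the mean of CPM per cell.

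Among single genes of blood progenitor-like cells that met the same minimums, fabp11a, a fatty acid-binding protein, had 236 UMIs in 9.06% of uninjected cells. It had 0 UMIs in the vegfc MO library, 24.98-fold lower against the floor of 3 UMIs, with an interval of the log2 ratio that ended at -4.33. The chemokine cxcl19 (-2.85), hey2 (-2.00), icn (-1.79) and the neuropeptide gene cort (-1.56) followed, together with the complex I subunits NDUFB1, mt-nd3, mt-nd1 and ndufa5 (-1.76 to -1.50) and klf11a (-1.45). The highest were the tubulin tubb5 (9.48 and 226 CPM, log2 ratio 4.58), cebpd (2.86), prdm1a (2.74), rrad (2.66), scpp8 (2.64), vat1 (2.24), the linker histone h1f0 (2.23), the retromer subunit vps26a (2.16), lmod1a (2.15) and tcima (2.08).

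Of 9 lower genes measured in at least 4 other classes, NDUFB1, mt-nd3, mt-nd1, ndufa5 and icn had ratios below 0 in each of the 8. The nearest to 0 were -0.27, -1.07, -0.94, -0.785 and -0.09 in the same order. Of the 10 higher genes, lmod1a was higher in every other class where it was measured, and the ratios of tubb5 and rrad were above 0 in all such classes but as low as 0.16 and 0.08. Some of these values turned or shrank with the cells taken. With each library clustered on its own, fabp11a was -0.26 and cxcl19 0.04, and with the highest doublet scores removed cebpd was -0.71 and tubb5 1.86.

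The gene behind the GFP reporter, itga2b, was lower in thrombocyte-like cells of the vegfc MO library, and so was the reporter. The level of itga2b was 51.2 CPM (45.9 to 56.9) and 28.2 CPM (19.8 to 39.0), a log2 ratio of -0.86 (-1.40 to -0.36), and that of EGFP 9013 and 4163 CPM. Both differences lay in cluster 9 (itga2b 63.1 and 17.6 CPM, EGFP 12383 and 1936 CPM) and not in cluster 8 (itga2b 42.0 and 38.5 CPM, EGFP 6409 and 6310 CPM). Blood progenitor-like cells had 765 and 826 CPM of EGFP, and 6 and 1 UMIs of itga2b. The von Willebrand receptor subunit gp1bb was at 195 and 125 CPM and mpl at 111 and 93.2 CPM in thrombocyte-like cells, and the thrombocyte list had -0.07 (2.67 percentile).

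Cells with UMIs of both an endothelial and a blood transcript, the pattern sought by the double-positive gate, were rarely detected in each library. Detection of itga2b was itself sparse, with a UMI in 24.2% and 14.4% of thrombocyte-like cells before thinning. Counts of kdrl together with itga2b therefore cannot show how rare such cells were. At 1500 UMIs, kdrl and itga2b were found together in 1 of 3474 uninjected cells (0.0288%) and in 0 of 2324 vegfc MO cells. Where 0 cells were found, the limit was set at 3 cells and not at the end of the exact interval. For the vegfc MO library that limit is a share of 0.129% of cells with both UMIs at this depth. Unthinned shares were 0.337% (0.180 to 0.576) and 0.151% (0.0412 to 0.386), and 380 and 324 shallower cells were left out of the thinned ones. The reporters mCherry and EGFP were found together in 0.345% (0.179 to 0.603) and 0.430% (0.206 to 0.790) of thinned cells, and in 2.96% (2.45 to 3.54) and 1.85% (1.37 to 2.44) of unthinned cells, so their order turned with depth. In mesenchyme- or cartilage-like cells, both reporters met in 0 of 603 and 0 of 631 thinned cells, and kdrl met itga2b in none either. The limit of 3 cells is a share of 0.498% and 0.475% there, too wide a range to set a background for the shares over all cells. Median depths were 6714 and 6679.5 UMIs over all cells.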

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

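The signal below was looked at only after the clusters were seen. The EGFP reporter, under the cd41 promoter, appeared at 1531 CPM in cluster 23, a neural-like cluster, of the uninjected library, outside the blood classes that the report compares. There, 50.4% (41.0 to 59.8) of 117 cells carried an EGFP UMI and 29 cells carried at least 10, at a median depth of 5556 UMIs. In the vegfc MO library the same cluster held 240 CPM, and 7.14% of 56 cells carried a UMI, at a median depth of 4234 UMIs. Outside the blood classes EGFP UMIs were widespread at low levels: in the mesenchyme-like cluster 5, 41.2% of uninjected cells carried one (147 CPM, median depth 5676 UMIs), and in the epidermal-like cluster 17, 38.2% (47.3 CPM, 11860.0 UMIs). The mesenchyme-like cluster 14 stood at 634 and 28.3 CPM, but 5.88% of its uninjected and 14.5% of its vegfc MO cells carried an EGFP UMI. Of its 153 uninjected cells, 1 carried at least 10, so the 634 CPM rests on few cells. The other neural-like cluster, 24, stood at 18.9 and 4.95 CPM, and thrombocyte-like cells at 9013 CPM in the uninjected library. The unnamed cluster 26 held 1003 CPM in 25 uninjected cells. The difference between the libraries in cluster 23 was not tested, and no explanation was tested for it.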

How the results depend on the processing

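A value counts as reversed where its 95% interval left out 0 and the alternative changed its sign, as kept where the alternative lay within that interval, and otherwise as moved. A value whose interval held 0 can thus change sign and count as moved or kept. Of the values set against alternatives fixed in advance, 1508 single-gene and other side values were kept, 256 moved and 23 reversed. Of the main values 136 were kept, 40 moved and 3 reversed. Against alternatives chosen after the data were seen, 373 side values kept, 52 moved and 6 reversed, and 41 main values kept and 8 moved. No paired analysis was possible because each group holds 1 library (the number 1 only names it). Clustered on its own, the vegfc MO library had no thrombocyte-like cluster, so that alternative gave no value for its thrombocyte-like share. The cause was not tested for any of the values below. Depth limits sparse genes most, such as runx1 in endothelial-like cells. Below, EC means endothelial-like cells, BP blood progenitor-like cells and TH thrombocyte-like cells, gene and list values are log2 ratios, and shares are percent of cells.

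Main values that reversed by this rule were the Vegf list in EC with members of at least 1 UMI (-0.0933) and the arterial list in EC with the mean of CPM per cell (-0.04861) and with median-of-ratios scaling (-0.01275). Main values with intervals that held 0 and that changed sign were the Notch list in BP, with cells thinned (-0.2816) and with the mean of CPM per cell (-0.5386), and the haemogenic list in BP with median-of-ratios scaling (-0.112).

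With at least 500 genes and at most 5% mitochondrial UMIs, reversals were fosl1a in BP (0.4432), mt-cyb in EC (0.06696) and the Erk list in EC (0.0002822). The arterial and venous difference moved to 0.6673, the arterial list in EC to 0.436, mitochondrial genes in EC to -0.842, ribosomal genes in EC to -0.4256 and the Notch list in BP to 0.3987. Uninjected shares moved to 17.71% for EC, 10.48% for BP and 12.06% for TH.

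At resolution 0.5 the Notch list in BP was 0.228 and the uninjected BP share 10.17%. At resolution 2 fosl1a in BP reversed (0.2206), the Notch list was 0.2088 and the uninjected shares 9.549% for BP and 8.407% for TH. With all genes open to clustering, apln (-0.2816) and fosl1a (0.1214) reversed in BP, the Notch list was 0.3208, the uninjected BP share 9.652% and the vegfc MO TH share 4.834%. With doublets kept, the vegfc MO BP share was 3.73%.

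With each library clustered on its own, cxcl19 (0.03518), gp1bb (0.4445) and the thrombocyte list (3.384) reversed in BP. The Notch list in BP was 0.2356, ribosomal genes in EC -0.3573, and BP shares 8.044% and 7.855%.

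Thinned to 1500 UMIs, reversals were EGFP in cluster 13 (0.1066), runx1 in TH (0.4819), and in BP smad6a (-0.9244), tal1 (-0.4099), the S phase list (-0.08795) and the arterial list (-0.1135). The ratio of vegfc in EC moved to 1.637 and mitochondrial genes in EC to -0.8374.

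With the mean of CPM per cell, reversals were EGFP in cluster 13 (0.1453), mt-cyb in EC (0.04501), and in BP the Erk list (-0.02368) and the S phase list (-0.00267). The arterial and venous difference was 0.05351, mitochondrial genes in EC -0.8192 and ribosomal genes in EC -0.1367.

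With median-of-ratios scaling, reversals were myb in TH (-0.04091), the S phase list in BP (-0.09126) and the unfolded protein response in EC (-0.002229). Mitochondrial genes were -1.398 in BP and -1.206 in EC, ribosomal genes in EC -0.4649 and the venous and lymphatic list in EC -0.3962. Without haemoglobin, ribosomal and mitochondrial genes in the total, ribosomal genes in EC were -0.3568.

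With list members of at least 1 UMI, the thrombocyte list in BP reversed (0.06994). With 5 G2 and M phase UMIs asked for, shares were 29.39% and 32.26% in BP and 14.31% and 11.99% in EC. With 2 UMIs of each gene, kdrl and itga2b met in 0% of uninjected cells, and unthinned in 0.3373%. With a minimum of 20 UMIs alone, 0 named genes in EC and 2 in BP were shared with the rule used.

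Among alternatives added after the data were seen, clusters 4 and 13 as 1 class gave cxcl19 at 0.3331 and her15.1 (ENSDARG00000054562) at -0.1862, both reversed, and BP shares of 11.7% and 6.684%. Leaving the compared lists out of clustering reversed fosl1a in BP (0.2763) and gave BP shares of 6.279% and 3.474%. Removing the highest 5% of doublet scores reversed cebpd (-0.7058), her15.1 (-1.272) and socs3a (-0.04283) in BP, with mitochondrial genes in BP at -1.378 and an uninjected BP share of 10.09%. Reporter transcripts gave double-positive shares of 0.3454% and 0.4303%.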

Other observations

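Of the tests below, those of doublets with lyz and of the 10th percentile of the mitochondrial share were written before their results were seen, and all others were chosen after. Several repressor genes of the Notch list were lower in the unnamed blood cluster 13 of the vegfc MO library, and not in all blood clusters. The Notch list there had a median of -0.58 at the 0.01 percentile, and her6 (2032 and 695 CPM), her9 (772 and 259 CPM) and hey2 (118 and 26.8 CPM) were lower. The copies of her15.1, a symbol shared by 2 identifiers, were at 71.3 and 2.23 CPM (ENSDARG00000054562) and 102.0 and 3.35 CPM (ENSDARG00000054560). Thrombocyte-like cells had a Notch list median of -0.51 (0.02 percentile), with her6 at 1991 and 1333 CPM. In blood progenitor-like cells her6 was level, at 1622 and 1606 CPM, and her9 was higher in cluster 2, at 366 and 1122 CPM. In blood progenitor-like cells her15.1 (ENSDARG00000054562) had no stable direction, at 40.2 and 80.1 CPM but with a log2 ratio of -1.272 when the highest doublet scores were removed. In endothelial-like cells her6 was at 21636 and 14509 CPM and her9 at 4699 and 2884 CPM.

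Lists of stress and division genes were higher in some blood clusters of the vegfc MO library. The unfolded protein response was higher in cluster 13 (0.60, 99.9 percentile), with chac1 (0.12, -0.01 to 0.25) the 1 member of 16 below the bulk of genes, and in thrombocyte-like cells (0.68, 100 percentile), where the chaperone hspa5 was at 370 and 921 CPM. The G2 and M phase list had 0.69 in cluster 13, with 24 of 25 members at ratios above 0, not all of which need lie above the bulk of genes. In erythroid-like cells the list had 1.03. In thrombocyte-like cells it had 0.39 (94.1 percentile), with ccnb1 lower, at 23.4 and 14.1 CPM.

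Neutrophil transcripts were higher in endothelial-like and blood progenitor-like cells of the vegfc MO library, and for lyz free RNA of neutrophils fits: endothelial-like cells stood at 1.054 times the median of 4 unrelated classes. Neutrophils or doublets within the endothelial-like clusters do not account for lyz, since the 5% of cells with most of it held 24.82% of its UMIs. The test was run for scpp8 and mmp9, picked after their values were seen. For these, free RNA is not enough in blood progenitor-like cells, since the smaller of their parts of the neutrophil level was 49.06 times that of lyz. Of the others, npsn (0.0653%) and mpx (0.113%) stood near lyz (0.0702%). Not so il6r (22.5%), srgn (6.71%) and cebp1 (5.04%), which also stood far above lyz. In the uninjected library il6r (23.55%), cebp1 (8.305%), srgn (4.68%), scpp8 (4.195%) and mmp9 (0.891%) exceeded lyz (0.0200%) too. The test therefore does not bear on the difference between the libraries. Expression of scpp8 and mmp9 by the progenitors, an effect of the vegfc MO and doublets among blood cells stay open, untested and confounded with the library.

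Mitochondrially encoded transcripts were lower as a list in all classes of the vegfc MO library, although mt-cyb was only slightly lower in endothelial-like cells (2769 and 2582 CPM) and level or higher elsewhere, at 2018 and 2027 CPM in blood progenitor-like cells, 2067 and 2181 CPM in thrombocyte-like cells and 1895 and 2132 CPM in cluster 13. More damaged cells in the uninjected library were tested for in endothelial-like cells only. There, the 10th percentile of the mitochondrial share was 0.763% and 0.389%, a log2 ratio of -0.9701, so a minority of damaged cells does not account for all of the difference. Damage shared by most cells could shift that percentile too. Higher up the shares differed by a smaller factor, with medians of 2.565% and 1.93% and 90th percentiles of 7.17% and 5.75%. The share sums UMIs over genes within a cell, so it is another measure than the list median. Over 10% mitochondrial UMIs were found in 12.6% of uninjected and 5.31% of vegfc MO barcodes. Stricter cell filters moved the list in endothelial-like cells to -0.842, so a part from damage is not excluded. Mitochondrial transcripts in free RNA do not account for all of the lower list. Cells with at least 10000 UMIs had a median over 7 classes of -0.9807, against -0.9516 over 5 partly different classes in the shallowest cells. Endothelial-like cells were left out, and blood progenitor-like cells went from -1.87 in shallow to -1.15 in deep cells, so a part from free RNA is not excluded. Ribosomal protein genes were also lower as a list in blood progenitor-like and thrombocyte-like cells and cluster 13, and a difference in library preparation, in injection or in the vegfc MO itself stays open, untested and confounded with the library.

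Class shares differed between the libraries, with fewer thrombocyte-like cells in the vegfc MO library. Carry-over of cells with neither reporter does not account for this alone, since thrombocyte-like cells per endothelial-like cell stood at 0.4739 (0.3668 to 0.6092) of the uninjected value. Pooling of the sorted fractions in other proportions cannot be told apart: thrombocyte-like cells per blood progenitor-like cell stood at 0.5538 (0.4048 to 0.7574), but mCherry was found in 13.9% of the former and 4.71% of the latter in the uninjected library, so the fractions need not hold them alike. A gate that left out the brightest GFP cells also stays open, since EGFP in cluster 8 stood at 0.9844 and in cluster 9 at 0.1564 of the uninjected level. An effect of the vegfc MO on thrombocyte-like cells or of injection as such stays open, untested and confounded with the library.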
